A study of Mus musculus with 4 samples.

How the data were processed

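Thymosphere RNA from 4 mouse samples was measured on 4 Agilent 1-colour arrays of 1 slide, 2 with RNA from adult and 2 with RNA from embryonic spheres. Per the labels' protocols, thymus digests were plated in ultra low attachment dishes with a medium that held epidermal and fibroblast growth factor, fresh medium was added on day 5, spheres were lysed after 7 days, and 25 ng of total RNA was labelled with Cy3. Groups were taken from the sample titles. The labels mention biological as well as technical replicates without saying which arrays are which.

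The scanner files hold intensity values per spot. Per the file headers, the intensity was extracted with Agilent Feature Extraction 10.7.3.1, which subtracted background and removed a spatial trend within each array, and no step between arrays had been applied to it. The deposited value table holds intensity on a linear scale, with the same maximum on all 4 arrays and medians of 34.4, 35.0, 35.7 and 35.1. Set against the scanner values, its log2 values correlated with the median spot signal of the same array at 0.994 to 0.998, more closely than with any other array. Its processing is not given in the sources used here, and how it was centred stays unknown. It served only as an alternative.

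Signals were used as log2 of the processed signal minus the array's 75th percentile, which was 132, 66.0, 126 and 61.5 on adult arrays 1 and 2 and embryonic arrays 1 and 2. Control spots and spots marked as outliers by Feature Extraction were left out, of which adult array 2 had 2756, against 185 on adult array 1 and 120 and 95 on the embryonic arrays. No spot was saturated. Spots of one probe were averaged, which gave 55681 probes. Through their RefSeq accessions, with versions removed on both sides, 28026 probes (50.3%) were matched to a gene symbol of the mouse annotation GRCm38.p6, used for names only, and these stood for 21154 genes. The other 27655 probes, among them those for intergenic regions, entered no gene test.

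A probe was tested if it was well above background on both arrays of at least 1 group, and each gene was represented by the probe of highest mean signal, probes measured on all 4 arrays first. Of 1375 called genes with more than 1 tested probe, 123 had called probes of opposite direction. Embryonic minus adult was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with p adjusted by the Benjamini-Hochberg method over 13667 genes and a threshold of 0.05. All 4 arrays entered the fit, without covariates. A gene not well above background on either array of a group has only a bound there. Its fold change is given as at least the bright group's mean over the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. This bound holds for the scaling used here and leaves out the error of the means.

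Before the data were examined, 30 gene lists, the tests and a rule for named genes were fixed. The lists cover thymic epithelial identity, epithelial keratins and junctions, fibroblasts and mesenchyme, adipocytes, smooth muscle and pericytes, neural crest and glia, the T lineage, macrophages and myeloid cells, MHC class II presentation, the B lineage, endothelium, erythroid cells, skeletal muscle, parathyroid, cartilage and bone, the cell cycle, its inhibitors and senescence, imprinted growth genes, fetal RNA-binding and chromatin genes, pluripotency, targets of Wnt, Notch, Hedgehog and BMP signalling, interferon response, inflammatory response, hypoxia and glycolysis, cholesterol synthesis, immediate early and heat shock genes, and matrix metalloproteases with their inhibitors. Lists with at least 4 tested genes were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Both used the genes measured on all 4 arrays, 13405 in number. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. With an estimated correlation camera takes its degrees of freedom from the arrays, so with 4 arrays it can hardly call a list.

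The named genes are the 10 highest and 10 lowest log2 fold changes among called genes with proper symbols that were well above background on all 4 arrays and whose groups did not overlap, the 5 greatest bounded folds per direction, up to 3 called members per direction and list, and 12 genes chosen beforehand whatever their values (Foxn1, Epcam, Krt5, Krt8, Trp63, Pdgfra, Col1a1, Ptprc, Igf2, H19, Sox2 and Plet1). Ddx3y, Xist and Meg3, and the listed genes named only as undetected, were named outside this rule, after their values were seen. Some genes that the rule takes are not reported here.

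Alternatives were normexp background correction (offset 50), quantile normalization, centring on the median of all probes, the deposited value table, no filter on dim probes, a filter asking for all 4 arrays, the mean of a gene's probes, an intensity trend or a robust prior in eBayes, the replicate number as a block, and leaving out each array. Setting the median of the tested genes to 0 on each array was added after seeing the data. Normexp was planned on mean spot signals and was run on median spot signals, the ones used here. Slide could not be tested as a batch, as all arrays share 1 slide.

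The fit was tested on simulated data for the comparison of embryonic with adult spheres over 13405 genes. With 4000 genes changed, 39.2%, 73.1% and 93.8% of those shifted by 1, 2 and 4 log2 units were recovered, and 4.50% of the calls were unchanged genes. With 200 genes changed, 0% were recovered at 1 and 2 units and 39.4% at 4, with 0 unchanged genes called. In the list test, run with 200 genes changed, 3.50% of unchanged lists had an unadjusted p under 0.05, and 100% of lists of 15 genes shifted by 1 unit did. Far more genes differed on the real arrays, which widens the spread a list is set against, so the 100% does not carry over to them. The simulated genes also varied independently of each other, so the simulation does not test lists whose genes vary together. In the real lists the estimated correlation ran from -0.09 (Wnt targets) to 0.84 (cell cycle).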

Results

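Thymospheres are free-floating aggregates that form when dissociated thymus cells are grown in culture dishes to which cells do not attach. Messenger RNA was measured in spheres grown from the thymus of adult mice, 5 to 6 weeks old, and from the thymus of embryos at embryonic day 14.5, both of the C57Bl6/N strain, after 7 days of culture. Each group had 2 samples, and each sample was hybridised to its own 1-colour array, so the data are 4 arrays on 1 slide. The comparison asks which transcripts set embryonic thymospheres apart from adult ones. The number of spots well above background was 42460 (71.6%) and 29410 (49.6%) on the adult arrays and 28657 (48.3%) and 21176 (35.7%) on the embryonic arrays. The small number of arrays limits the precision. The labels do not separate biological from technical replication, so p-values measure only the spread between these samples, which may be technical. Adult and embryonic arrays lay at separate positions of the slide, and position and group cannot be told apart.

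Arrays of one group resembled each other more than arrays of different groups. Across 13405 genes the normalised log2 signal correlated with Pearson r of 0.959 between the adult arrays and 0.963 between the embryonic arrays, against 0.737 to 0.765 between the groups. The median absolute log2 difference was 0.33 and 0.41 within the groups and 1.15 to 1.23 between them. These correlations run across genes, which are not independent replicates, and no test was made on them.

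Embryonic thymospheres had far more transcript from imprinted growth genes and more from the listed keratin and junction genes, and adult thymospheres had more from interferon-induced genes. These lists were called in camera with the preset correlation, and none of them with an estimated correlation (adjusted p = 0.755, 0.844 and 0.69). Dlk1, an imprinted membrane protein of immature cells that was well above background on 1 of the 2 adult arrays, stood 7.63 log2 units higher in embryonic spheres (SE 0.88, adjusted p = 0.00984), and the cell cycle inhibitor gene Cdkn1c 5.76 higher (SE 0.30, adjusted p = 0.00984). The cytokine gene Il6 was lower by a log2 fold change of -4.85 (SE 0.50, adjusted p = 0.00984). Of 13667 genes tested with limma, 7159 (52.4%) differed, 4777 higher and 2382 lower in embryonic spheres, and 6901 of them by at least 2-fold. The groups did not overlap in 84.0% of the 13405 genes measured on all 4 arrays, where 33.3% of orderings of 2 against 2 arrays do so by chance. The 33.3% holds for 1 gene and is no expected share over genes that share the same arrays. A median shift of 0.76 and a filter that genes bright in 1 group pass also raise the 84.0%.

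The split between higher and lower calls rested on the scaling and on the filter. The median log2 fold change of the tested genes was 0.76, and 66.7% of calls were higher in embryonic spheres. With the median of the tested genes set to 0 on each array, 3824 genes were called, 1046 higher and 2778 lower (27.4% higher), and with each array centred on the median of all its probes 11526 were called, 9831 higher and 1695 lower (85.3% higher). With no filter on dim probes 829 of 2492 calls were higher (33.3%), and with signal asked on all 4 arrays 4993 genes were higher and 317 lower (94.0% higher). Every log2 fold change given here is embryonic minus adult and can be read against 0.76. No gene was called once either adult array was left out, although 5603 and 6019 genes had an unadjusted p under 0.05 in limma. Without the one or the other embryonic array 5470 and 5586 genes were called.

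Among the genes well above background on all 4 arrays, the 10 with the greatest rise in embryonic spheres were led by Cdkn1c. After it came Selenbp1, a selenium-binding protein gene (log2 fold change 5.12, SE 0.35), Lbhd2 (4.67, SE 0.35) and Ptn, which encodes the secreted growth factor pleiotrophin (4.61, SE 0.42). Evpl, for the desmosomal protein envoplakin, rose by 4.33 (SE 0.58) and the keratin gene Krt19 by 4.28 (SE 0.54). The retinol-oxidising enzyme gene Adh1 (4.21, SE 0.61), the TGF-beta family gene Gdf10 (4.18, SE 0.37), the semaphorin gene Sema5a (4.18, SE 0.35) and Itm2a (4.07, SE 0.36) completed this group. Their adjusted p lay between 0.00984 and 0.011, and all 10 were still called after centring on the tested genes.

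The 10 genes of this kind with the greatest fall were led by Il6. The chemokine gene Ccl8 changed by -4.72 (SE 0.29) and Mfap5, a microfibril component gene, by -4.03 (SE 0.57). Oasl1 (-3.55, SE 0.34) and Zbp1 (-3.19, SE 0.41) are interferon-induced, Ptgis makes prostacyclin (-3.40, SE 0.29), Cck encodes the peptide cholecystokinin (-3.36, SE 0.33) and Timp1 a metalloprotease inhibitor (-3.17, SE 0.32). The olfactory receptor gene Olfr1383 also fell (-3.68, SE 0.61, adjusted p = 0.0128), and the other adjusted p of this group lay between 0.00984 and 0.0107.

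Some genes were measured in one group and not well above background on either array of the other, so their change is a lower bound. In embryonic spheres Igf2, the fetal insulin-like growth factor, was at least 48.8-fold higher, the neuropeptide precursor gene Pnoc at least 25.0-fold, the angiotensin receptor gene Agtr2 at least 24.3-fold, the Y-linked translation factor gene Eif2s3y at least 20-fold and the imprinted gene Peg3 at least 19-fold. Their adjusted p lay between 0.00984 and 0.0104. In the other direction Gpr35 was at least 30.0-fold higher in adult spheres, Hdgfl1 at least 27.7-fold, the olfactory receptor gene Olfr481 at least 26.1-fold, Fbll1 at least 25.5-fold and A4gnt at least 24.2-fold, with adjusted p from 0.00984 to 0.0111. These bounds belong to the scaling used here. Over the alternatives the fitted log2 fold change came down to 3.14 for Igf2, 2.40 for Pnoc and -3.01 for Gpr35, smaller changes than their bounds. Of the genes called lower in embryonic spheres, 1710 (71.8%) were not well above background on either embryonic array, and 179 of those called higher were not so on either adult array.

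Adult arrays showed signal on probes for many genes that are mostly restricted to sensory cells. Of 1500 probes for olfactory, vomeronasal, taste and trace amine receptor genes, 51.3% and 23.1% were well above background on the adult arrays and 6.07% and 2.20% on the embryonic arrays. Of 327 such genes tested, 284 were called lower and 6 higher in embryonic spheres, which makes 11.9% of all genes called lower. The filter favoured lower calls here, since 324 of the probes were well above background on both adult arrays and 32 on both embryonic arrays. The percentages of all 1500 probes do not depend on that filter. This adult signal stands beside each group of adult-higher genes whose members were dim on the embryonic arrays.

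**Figure D1:**
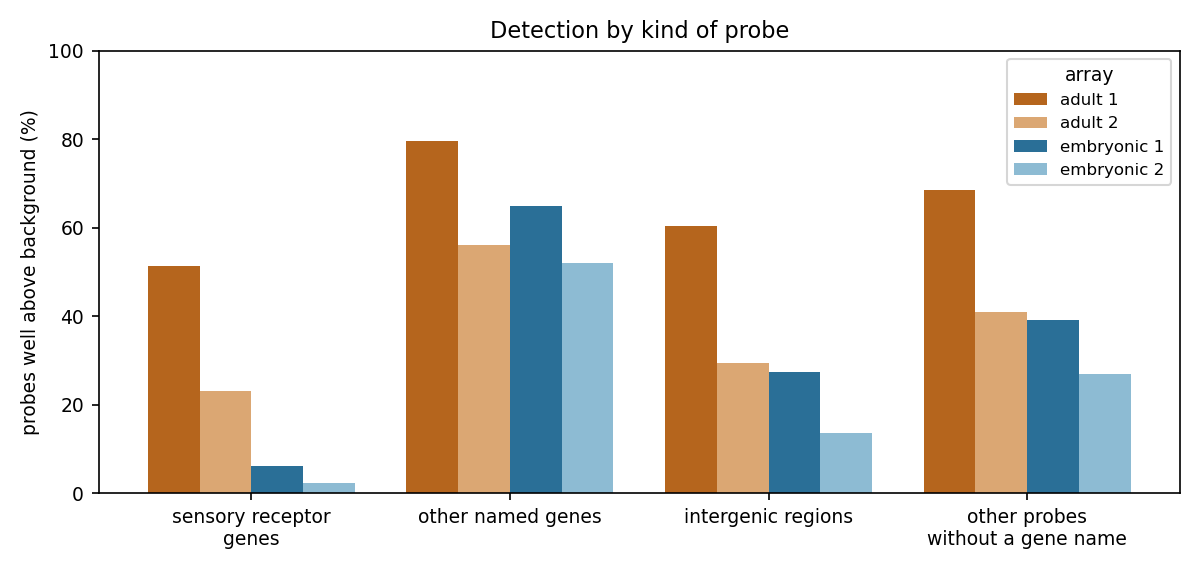
Bars give the percent of probes well above background (vertical axis) on each of the 4 arrays for 4 kinds of probe (horizontal axis). Sensory receptor probes reached 51.3% and 23.1% on the adult arrays against 6.07% and 2.20% on the embryonic arrays.

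Imprinted genes that control growth rose together in embryonic spheres. Of 13 tested, 11 were called higher and none lower, with the same 11 when adjusted over the list alone and 9 still higher after centring on the tested genes. Among them were Dlk1, Cdkn1c and, with only a lower bound, Igf2 and Peg3. The list was shifted upward in camera with the preset correlation (adjusted p = 0.00133), and not with an estimated correlation (adjusted p = 0.755). Over the 7 members well above background on all 4 arrays, 6 were called higher and the camera call was lost (adjusted p = 0.0796). Meg3, among the 11, rose on the probe used (3.36, SE 0.35, adjusted p = 0.00984), while another of its called probes fell (-1.98). The imprinted RNA gene H19 was not matched to a probe.

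The listed genes of epithelial keratins and cell junctions were mostly higher in embryonic spheres. Of 23 tested, 15 rose and 1 fell, 15 and 1 when adjusted over the list alone, and 8 and 1 after centring. Krt19, the epithelial transcription factor gene Elf3 (3.60, SE 0.74), the desmosomal gene Perp (3.25, SE 0.64) and the basal keratin gene Krt5 (3.22, SE 0.48) rose, while Krt14, the usual partner of Krt5, fell (-1.91, SE 0.46, adjusted p = 0.024). The list's adjusted p was 0.0348 with the preset correlation and 0.844 with an estimated correlation, and it was no longer called over genes well above background on all 4 arrays (adjusted p = 0.213), without adult array 2 (adjusted p = 0.0744) or without embryonic array 2 (adjusted p = 0.0594), which are 3 of 15 alternatives. Elf3 was well above background on 1 of the 2 adult arrays. Krt8 rose by 1.78 (SE 0.35, adjusted p = 0.0165), a call lost after centring (adjusted p = 0.0716). The epithelial surface marker gene Epcam (log2 fold change 0.89, SE 0.42, adjusted p = 0.123) and the basal cell factor gene Trp63 (1.32, SE 0.57, adjusted p = 0.101) did not pass the test. Keratin genes as a whole did not rise. Of 34 tested genes with symbols beginning Krt, 11 were higher and 11 lower, with a median log2 fold change of 0.03. Camera with the preset correlation did not call this family (adjusted p = 0.134). Over the 21 of them well above background on all 4 arrays, the median lay 0.28 above that of such genes.

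Transcription factor genes of thymus and pharyngeal pouch development were among those higher in embryonic spheres. Tbx1 rose by 3.42 (SE 0.37), Pax1 by 3.20 (SE 0.37) and Pax9 by 3.20 (SE 0.34), each with an adjusted p of 0.00984, and the progenitor marker gene Plet1 by 2.80 (SE 0.46, adjusted p = 0.0128). Foxn1, the master regulator of thymic epithelium, rose by 2.03 (SE 0.37, adjusted p = 0.0143), and this call was lost after centring (adjusted p = 0.0527). Tbx1, Pax9 and Foxn1 were each well above background on 1 of the 2 adult arrays. Of 14 tested members of the thymic epithelial list 7 rose and none fell, 6 when adjusted over the list alone, and after centring 5 were higher and 1 lower. The list missed the threshold in camera (adjusted p = 0.0779, and adjusted p = 0.756 with an estimated correlation), and passed it in fry (adjusted p = 0.0417) and in camera after quantile normalization (adjusted p = 0.00737). Probes for Aire, Psmb11 and Dll4 were on the array and were not well above background on both arrays of either group.

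Interferon-induced genes were lower in embryonic spheres as a group. Of 16 tested, 12 fell and none rose, 14 when adjusted over the list alone, and 13 after centring. Oasl1, Zbp1 and Ifi27l2a (-2.88, SE 0.51, adjusted p = 0.0139) changed most. None of the called members was dim on both embryonic arrays, and of 10 members well above background on all 4 arrays 8 fell, or 9 when only genes with signal on all 4 arrays were tested. The list had an adjusted p of 1.93e-07 in camera with the preset correlation and an adjusted p of 0.69 with an estimated correlation.

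Inflammatory genes fell in part. Of 14 tested, 4 fell and 1 rose, the same numbers when adjusted over the list alone, and 4 and 0 after centring. Il6 fell, Il1a was at least 5.97-fold higher in adult spheres (adjusted p = 0.0187), the neutrophil chemokine gene Cxcl2, well above background on 1 of the 2 embryonic arrays, fell (-1.76, SE 0.49, adjusted p = 0.0344), and Tnfaip3, which restrains NF-kappaB signalling, rose (1.44, SE 0.32, adjusted p = 0.0204). The list's adjusted p was 0.0448 with the preset correlation and 0.844 with an estimated correlation, and the call was lost in 5 of 15 alternatives, among them without adult array 2 (adjusted p = 0.0744) and without embryonic array 2 (adjusted p = 0.561). Among matrix metalloproteases and their inhibitors, 4 of 12 tested genes fell and 1 rose (3 and 1 adjusted over the list alone). Timp1 fell, Mmp13 was at least 3.22-fold higher in adult spheres (adjusted p = 0.00984) and Timp3 rose by 1.90 (SE 0.50, adjusted p = 0.0307), a call lost after centring (adjusted p = 0.111). That list was not called (adjusted p = 0.2), but was after quantile normalization (adjusted p = 0.0438).

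**Figure D2:**
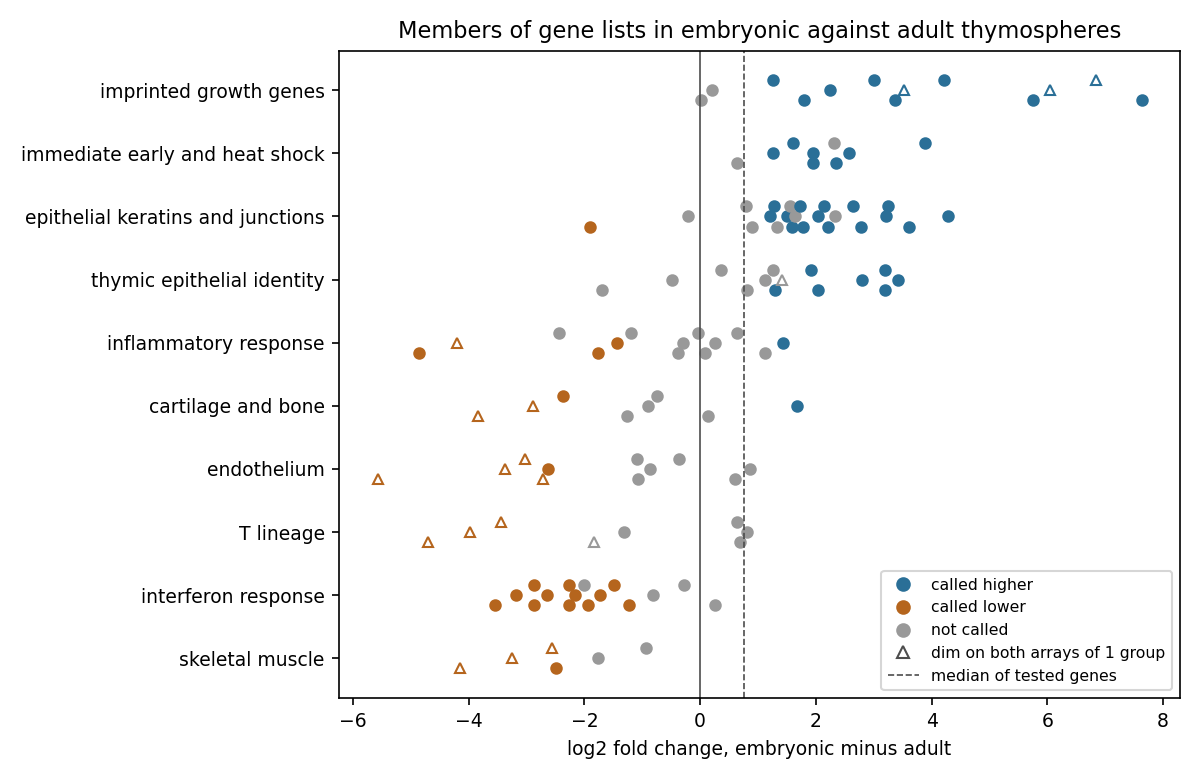
Each point is the log2 fold change, embryonic minus adult (horizontal axis), of 1 tested gene of the 9 lists called by camera and of the thymic epithelial list (vertical axis). Triangles mark genes not well above background on either array of 1 group. They are drawn at the fitted value and not at the lower bound given in the text, so they can overstate the change. In the imprinted list 11 of 13 genes were called higher, and in the interferon list 12 of 16 were called lower, against a tested median of 0.76.

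**Figure D3:**
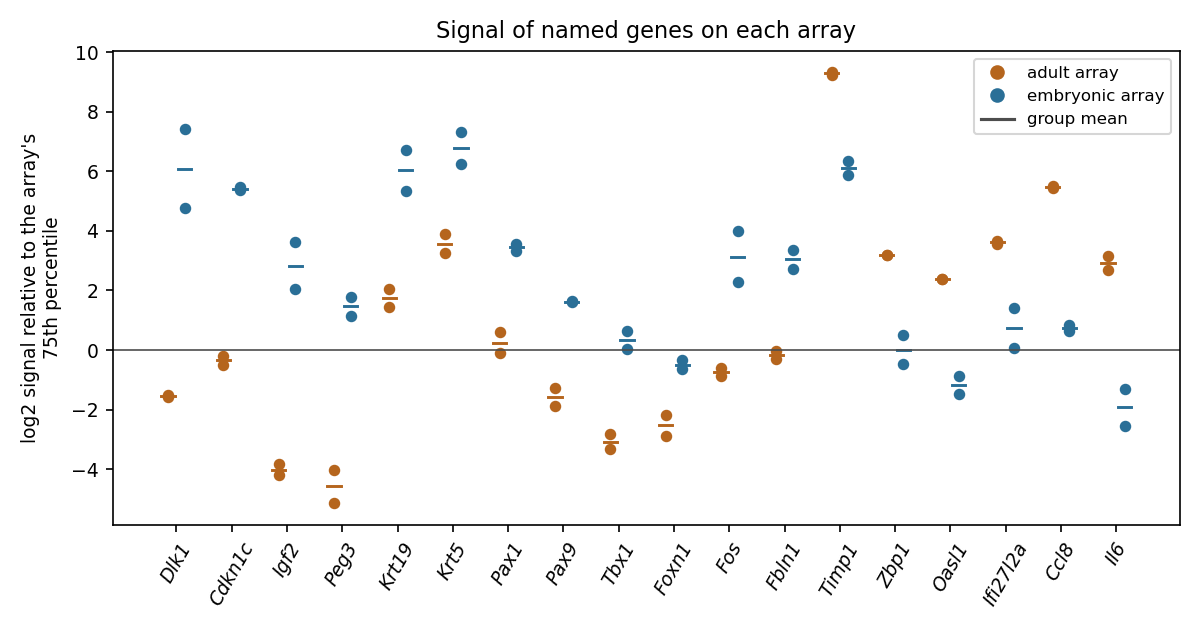
Points give the log2 signal relative to the array's 75th percentile (vertical axis) of named genes (horizontal axis) on each of the 2 adult and 2 embryonic arrays, and short lines the group means; Igf2 and Peg3 were not well above background on the adult arrays. Dlk1 and Cdkn1c lay higher on both embryonic arrays by 7.63 and 5.76 in the mean, and Il6 lower, with a log2 fold change of -4.85.

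Fibroblast genes were detected in both kinds of sphere and most were not called, which does not show that their levels were alike. Of 28 such genes on the array, 27 were well above background on both adult arrays and 26 on both embryonic arrays. Of 27 tested, 6 rose and 1 fell, the same when adjusted over the list alone, and 5 and 1 after centring. The matrix genes Fbln1 (3.20, SE 0.35), Lum (2.43, SE 0.30) and Col6a2 (2.35, SE 0.42) and the growth factor receptor gene Pdgfra (2.19, SE 0.37) rose, and the surface marker gene Thy1 fell (-1.45, SE 0.39, adjusted p = 0.0309). Col1a1 had a log2 fold change of 0.53 (SE 0.35, adjusted p = 0.24), and its sign turned under quantile normalization. The list was not called in camera (adjusted p = 0.877).

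Several lists of other mesodermal tissues were lower in embryonic spheres, and most of their called members were dim on both embryonic arrays. In the skeletal muscle list 4 of 6 tested genes fell, 3 of them dim in this way, namely Ttn (at least 3.59-fold higher in adult spheres), Tnnt3 (at least 5.10-fold) and Mylpf (at least 4.21-fold). In the endothelial list 5 of 11 fell, 4 of them dim, among them Esam (at least 14.8-fold), Robo4 (at least 2.69-fold) and the vascular cadherin gene Cdh5 (at least 2.70-fold). In the cartilage and bone list 3 of 8 fell, 2 of them dim, and 1 rose. Col10a1 was at least 3.63-fold and Col9a1 at least 2.38-fold higher in adult spheres, Runx2, well above background on 1 of the 2 embryonic arrays, fell (-2.37, SE 0.50, adjusted p = 0.0182), and Sox9 rose (1.68, SE 0.37, adjusted p = 0.0201), a call lost after centring (adjusted p = 0.0877). Counts adjusted over each list alone were the same. Camera's adjusted p was 0.00111 for skeletal muscle, 0.00112 for endothelium and 0.0389 for cartilage and bone, against adjusted p of 0.69, 0.69 and 0.844 with an estimated correlation, and the cartilage call was lost in 7 of 14 alternatives, among them without adult array 2 (adjusted p = 0.0594) and without embryonic array 1 (adjusted p = 0.139). When only genes with signal on all 4 arrays were tested, the endothelial list was still called over its 5 such members (adjusted p = 0.0094), 2 of them lower and 1 higher. The members dim on both embryonic arrays go with the sensory receptor probes, 284 of whose 327 tested genes were lower in embryonic spheres, a count that the filter favoured.

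Adipocyte, smooth muscle and neural lists moved both ways. Of 17 adipocyte genes 7 rose and 6 fell (8 and 6 adjusted over the list alone), and after centring 1 and 6 did. Klf15 was at least 10.9-fold higher in embryonic spheres and Adipoq, which encodes adiponectin, at least 4.82-fold higher in adult spheres. Of 11 smooth muscle and pericyte genes 3 rose and 3 fell, the same adjusted over the list alone, and Acta2, smooth muscle actin, fell (-1.49, SE 0.32, adjusted p = 0.0189). Of 8 neural crest and glia genes 1 rose and 2 fell (1 and 1 adjusted over the list alone). The one that rose, the myelin gene Mbp (2.20, SE 0.36, adjusted p = 0.0128), depends on the probe, since its other 2 called probes fell (-1.35 and -2.55). Those that fell include the neuronal tubulin gene Tubb3 (-2.23, SE 0.39, adjusted p = 0.0138), which was well above background on 1 of the 2 embryonic arrays. None of these lists was called (adjusted p = 0.977, 0.698 and 0.439). Camera's direction was down for the adipocyte and smooth muscle lists, although their medians lay above that of the tested genes by 0.33 and 0.03, and up for the fibroblast list, whose median lay at -0.32 relative to it.

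Apart from macrophage genes, markers of blood cells were detected in part, more of them on the adult than on the embryonic arrays. The pan-leukocyte gene Ptprc was well above background on 1 adult array and on neither embryonic array, and was not tested. Of 21 macrophage and myeloid genes on the array, 14 were well above background on both adult arrays and 14 on both embryonic arrays. Of 15 tested, 4 rose and 1 fell (2 and 1 adjusted over the list alone), and 1 and 1 after centring. Lyz2, lysozyme, rose by 2.27 (SE 0.47, adjusted p = 0.0179) and the complement gene C1qc by 2.07 (SE 0.64, adjusted p = 0.0452), while the Fc receptor gene Fcgr1 was at least 3.57-fold higher in adult spheres (adjusted p = 0.0161). Centring ended the calls of Lyz2 (adjusted p = 0.0508) and C1qc (adjusted p = 0.144). The list was not called (adjusted p = 0.534).

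In the T lineage list 8 of 16 genes were well above background on both adult arrays and 3 on both embryonic arrays. Of 8 tested, 3 fell, all of them dim on both embryonic arrays and also called over the list alone. Of the 3 members well above background on all 4 arrays none was called, and their median was -0.24 relative to that of all such genes. Themis was at least 6.32-fold, Cd3g at least 3.51-fold and Ptcra at least 2.94-fold higher in adult spheres. The list's adjusted p was 0.0448, and 0.844 with an estimated correlation, and its call was lost in 5 of 14 alternatives, among them without adult array 2 (adjusted p = 0.0763) and without embryonic array 1 (adjusted p = 0.0596). Rag1, Cd8a and Dntt were not well above background on both arrays of either group. Of the MHC class II genes 1 of 6 tested fell and none over the list alone, and the list was not called (adjusted p = 0.288). The B lineage, erythroid and parathyroid lists had too few tested genes for camera. All 3 tested B lineage genes fell, of the erythroid genes 1 rose and 1 fell, and of 3 parathyroid genes 1 fell, with the same counts adjusted over each list alone. Apart from the B lineage gene Ebf1 (-1.35, SE 0.36, adjusted p = 0.0323), which was well above background on all 4 arrays, these adult-higher members were dim on both embryonic arrays and go with the sensory receptor signal as well.

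Immediate early and heat shock genes rose in embryonic spheres. Of 9 tested, 7 rose and none fell, 8 when adjusted over the list alone, and 3 after centring. Fos rose by 3.88 (SE 0.60), Egr1 by 2.58 (SE 0.35) and Atf3 by 2.35 (SE 0.41), with adjusted p from 0.0105 to 0.0137. The list's adjusted p was 0.0448 with the preset correlation and 0.844 with an estimated correlation, and the call was lost in 4 of 15 alternatives, among them without adult array 1 (adjusted p = 0.0517), adult array 2 (adjusted p = 0.0791) or embryonic array 2 (adjusted p = 0.0594).

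Proliferation genes were detected in both groups and lay close to the median of the tested genes. Of 24 cell cycle genes 8 rose and none fell, 0 when adjusted over the list alone and 0 after centring. Top2a rose by 1.89 (SE 0.55), Mcm3 by 1.80 (SE 0.39) and Mcm4 by 1.73 (SE 0.33), and after centring their adjusted p were 0.14, 0.0788 and 0.0559. Top2a was well above background on 1 of the 2 adult arrays. Of 11 cell cycle inhibitor and senescence genes 7 rose and 2 fell, the same over the list alone, and 3 and 2 after centring. The insulin-like growth factor binding protein genes Igfbp5 (3.53, SE 0.58) and Igfbp3 (2.62, SE 0.31) and the inhibitor gene Cdkn1b (2.40, SE 0.29) rose, and Igfbp7 (-2.02, SE 0.37) fell. Neither list was called (adjusted p = 0.1 and 0.497), although the cell cycle list was after quantile normalization (adjusted p = 0.0438).

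Of 15 genes of cholesterol synthesis 9 rose and none fell, 11 when adjusted over the list alone, and 3 after centring. Sqle rose by 2.66 (SE 0.37), Idi1 by 2.21 (SE 0.35) and Hmgcs1 by 2.20 (SE 0.34), and these were still called after centring. Of 13 hypoxia and glycolysis genes 3 rose and 1 fell (1 and 1 over the list alone). Ndrg1 rose by 2.31 (SE 0.49), a call lost after centring (adjusted p = 0.0536), and Ankrd37 fell (-1.61, SE 0.28). Neither list was called (adjusted p = 0.103 and 0.497), although the cholesterol list was after quantile normalization (adjusted p = 0.0438).

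Fetal RNA-binding and pluripotency genes did not move one way. Of 9 fetal RNA-binding and chromatin genes 4 rose and 2 fell, the same over the list alone. The RNA-binding protein gene Igf2bp1 was at least 5.61-fold and Igf2bp3 at least 10.5-fold higher in embryonic spheres, while Trim71 was at least 3.98-fold and Lin28b at least 2.39-fold higher in adult spheres. Of 9 pluripotency genes 1 rose and 3 fell, the same over the list alone. Klf4 rose by 2.21 (SE 0.48), a call lost after centring (adjusted p = 0.0631), the 3 that fell were dim on both embryonic arrays, among them Pou5f1 (at least 2.45-fold higher in adult spheres), and Sox2 was not well above background on any array. Neither list was called (adjusted p = 0.569 and 0.259). The adult-higher genes here again go with the sensory receptor signal.

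Targets of signalling pathways gave small counts. Of 7 Wnt targets 3 rose and none fell, and of 6 BMP targets 3 rose, led by Smad6 (2.72, SE 0.60, adjusted p = 0.02; well above background on 1 of the 2 adult arrays), with the same counts over each list alone and no higher call left in either list after centring. The rise of the Wnt target Nkd1 (1.43, SE 0.36, adjusted p = 0.0261; well above background on 1 of the 2 adult arrays) depends on the probe, as another called probe fell (-3.53). Neither list was called (adjusted p = 0.977 and 0.288). Of 3 Notch targets 1 fell, and both tested Hedgehog targets fell, each with the same count over the list alone, and these lists were too short for camera. Gli1 was at least 10.6-fold and Ptch1 at least 4.05-fold higher in adult spheres, with neither well above background on an embryonic array.

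Of 25 lists with enough tested genes, 9 were called by camera with the preset correlation, none with an estimated correlation (smallest adjusted p = 0.69, and 0 lists at an unadjusted p under 0.05), and 2 by fry, the imprinted and the thymic epithelial list (adjusted p = 0.0417 each). The version with an estimated correlation has little reach with 4 arrays. For skeletal muscle the estimate was -0.05, below the preset 0.01, and the unadjusted camera p still went from 8.89e-05 to 0.0568. The other called lists had estimates above the preset, from 0.05 (endothelium) to 0.58 (keratins and junctions). For them the small number of arrays and the correlation between genes cannot be told apart as the reason for the lost call. A call missing with an estimated correlation therefore does not decide whether correlated genes made the preset call. Of 429 listed genes on the array, 295 were well above background on both adult arrays and 263 on both embryonic arrays.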

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

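The test against the negative control spots was chosen only after the result was seen, and so were the values set beside the correlation of the adult arrays below. It was first run on the probes lit on both adult arrays, whose medians lay 21.8 and 13.0 SDs above the control spots, which decides nothing because those probes were picked for their signal. Differences of an adult and an embryonic array correlated with r = 0.721 and 0.703 for the 2 ways of pairing, which decides nothing either, because the embryonic arrays correlate with each other. The pairs of single probes were chosen after the strand ratio was seen too. A first version, same-strand pairs in all regions, was to count against label from both strands if its ratio passed 1.2, and gave 364 pairs with both lit against 303 expected, a ratio just above 1.2 by far less than its SD of 0.04, so it was not used.

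Probes for intergenic regions, which no comparison used, were well above background on both adult arrays in 4611 cases of 16194 (28.5%) and on both embryonic arrays in 2194 cases (13.5%), a signal in data outside the gene tests. None of the 308 negative control spots was well above background on any array.

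Sensory receptor probes also showed an excess on the adult arrays (324 of 1500 well above background on both, against 32 on the embryonic arrays), and the values argue against 1 of 3 technical explanations. Noise drawn separately on each array would leave the adult arrays uncorrelated across these probes, and they correlated with r = 0.768, a value that alone does not bear on the excess because the embryonic arrays reached 0.780, but adult with embryonic arrays gave only 0.170 to 0.268, and 324 of 1401 probes measured on both adult arrays were lit on both, against 165 for independent arrays with 674 and 344 lit. A background shared by the whole array stays open, since over all sensory receptor probes the median lay 6.45 and 2.59 SDs of the negative control spots above their mean on the adult arrays (0.78 and 0.81 on the embryonic arrays), with 1 array inside the bound of 3 set for it and neither past the bound of 10 set against it. Label made from both strands, as genomic DNA could give, stays open. Of 1067 intergenic regions with a probe per strand, 557 had both lit on the adult arrays. That is 1.07 times the number independent strands would give (1.16 on the embryonic arrays). The highest ratio possible was 1.42 on the adult arrays and 2.66 on the embryonic arrays. Both strands were lit in 59.8% and 27.7% of the lit regions. The adult and embryonic ratios therefore cannot be compared, and the adult ratio had little room to rise. The bound of at most 1.2 set against such label was wrong because same-strand pairs of single probes reached only 1.05 (SD 0.11). Pairs on opposite strands gave 0.91 (SD 0.11), a difference of 0.909 SDs, in each case without probes lit on both embryonic arrays. The age of the mice, the design's biological difference, also stays open and was not tested.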

How the results depend on the processing

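The tested-gene centring and its values were chosen after seeing the data, and all other alternatives before. Of 7159 called genes, 3401 kept call and direction under normexp, 4151 under quantile normalization and 3427 after centring on the tested genes. Normexp gave 3564 calls (2599 higher, 965 lower, 2665 at least 2-fold), quantile normalization 2855 higher genes, centring on all probes 11526 (all at least 2-fold, 9831 higher) and centring on the tested genes 3824 (all at least 2-fold, 1046 higher). These scalings place the median log2 fold change of the tested genes at 0.43, 0.30, 1.98 and 0.14, against 0.76. The deposited value table gave 4249 genes of at least 2-fold. With no filter on dim probes 21151 genes were tested and 2492 called, all at least 2-fold and 829 of them higher. Asking for signal on all 4 arrays left 317 lower genes and 4399 of at least 2-fold, since genes dim in 1 group are then not tested. For the other changes the cause was not tested.

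Leaving out 1 array gave from 0 to 5586 called genes (0 to 3399 higher, 0 to 2201 lower, 0 to 5586 at least 2-fold). The value 0 came without either adult array, where limma still gave 5603 and 6019 genes an unadjusted p under 0.05, and the lone array of a group is assumed to vary like the other group. Lists called numbered 4 to 9 in these fits, 4 with signal asked on all 4 arrays, 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 2 with fry, against 9. The interferon, endothelial and skeletal muscle lists were called in every alternative of the camera fit with the preset correlation in which they could be tested. For skeletal muscle this leaves out the fit that asked for signal on all 4 arrays. Only 2 of its 6 tested genes had such signal, so its call was never tried without genes dim in 1 group. The thymic epithelial list gained its call under quantile normalization, centring on all probes or on the tested genes, and in the deposited value table, the cell cycle, cholesterol and metalloprotease lists in 4, 5 and 3 alternatives, MHC class II without embryonic array 1 (adjusted p = 0.0373), and with no filter the B lineage (0.00705) and Hedgehog (0.0137) lists.

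With the replicate number as a block 6744 genes were called, and 6415 of the calls kept their direction. The numbers share no stated batch or day, and the deviations of same-numbered arrays correlated at 0.07, so the arrays are not taken as paired. The mean correlation between arrays of different groups was 0.892 under normexp and 0.855 in the deposited value table, against 0.752. The log2 fold change of Col1a1, which was not called, turned to -0.26 under quantile normalization, -0.31 in the deposited value table and -0.086 after centring on the tested genes. With the mean of a gene's probes Mbp turned to -0.57 and Nkd1 to -1.05, as their probes disagree, and in the deposited value table Nkd1 turned to -1.15. Among the other values of named genes, 1193 kept their side of the threshold, 304 lost the call and 12 gained it, none with a change of sign. Signal over background limits most lower calls, since 71.8% of those genes were not well above background on either embryonic array.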

Other observations

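Gene families that share the start of a symbol were scanned after the data were seen, and of the tests below only the one on sex was chosen before its result was known, while the reading of Xist relative to the tested genes was chosen after it.

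Of 75 families with at least 15 tested genes, 5 were shifted in camera with the preset correlation, which used only their genes measured on all 4 arrays (14 in the smallest families). Genes of translation initiation factors (symbols beginning Eif) were higher in embryonic spheres in 27 of 54 cases and lower in 1 (adjusted p = 0.0169, unadjusted p = 0.0545 with an estimated correlation), and over the 51 of them well above background on all 4 arrays their median lay 0.04 above that of such genes. Genes beginning Cyp, mostly cytochrome P450 enzymes, were lower in 15 of 39 cases and higher in 4 (adjusted p = 0.0442, unadjusted p = 0.0736 with an estimated correlation), and genes beginning Gpr, for G protein-coupled receptors, lower in 15 of 29 and higher in 5 (adjusted p = 0.0132, unadjusted p = 0.17 with an estimated correlation). Over the 22 Cyp and 11 Gpr genes well above background on all 4 arrays the medians were -0.18 and 0.09 relative to such genes, so the Gpr fall was not seen there. The olfactory and vomeronasal receptor families were the remaining ones, lower in 255 of 287 and 24 of 33 cases (unadjusted p = 0.151 and 0.216 with an estimated correlation). As for the sensory receptor genes as a whole, the filter favoured lower calls in these families. Only 15 and 5 of these genes were well above background on all 4 arrays, with medians of -0.58 and -0.35 relative to such genes.

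The lower level of interferon-induced genes in embryonic spheres was weighed against dim signal and against a difference in cell makeup. The values argue against dim signal seen on the adult arrays alone, because the members well above background on all 4 arrays had a median log2 fold change of -3.14 relative to that of all such genes. If interferon-induced transcripts came mainly from macrophages, which was not tested, fewer macrophages in the embryonic spheres would lower both lists about alike. The interferon list had a median of -2.84 relative to the tested genes. The macrophage and myeloid list had a median 0.20 above them (SD of its members 1.31), although the macrophage gene Fcgr1 was at least 3.57-fold higher in adult spheres. Without that premise the comparison decides nothing. An interferon response that differs with the age of the thymus is a hypothesis that may be followed and was not tested. A difference in culture, in other leukocytes, in the sex of the mice or in the position of the arrays was not tested either and stays open. A difference in macrophages stays open too where that premise fails.

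The Y-linked genes Eif2s3y and Ddx3y were at least 20-fold and at least 5.30-fold higher in embryonic spheres (adjusted p = 0.00984 and 0.0103), with neither well above background on an adult array, and, as the labels give no sex, a candidate explanation is a different sex makeup of the mice, with only females among the adult donors. The Y-linked genes Kdm5d and Uty were not well above background on any array, so the bound set against it beforehand, fewer than 3 of 4 such genes called higher, was wrong, as only 2 could be tested. Xist, made from the inactive X of females, had a log2 fold change of 1.59 (SE 0.54, adjusted p = 0.0556), a direction that the bound set against it named too, but without the shift of the tested genes it is 0.84 and within 2 SE of them. Fewer females among the embryos would lower Xist, and against this it kept its direction in all 15 alternatives and was called higher in 5 of them (0.73 to 2.82 over all), though not after centring on the tested genes (0.98, adjusted p = 0.2). The alternatives reuse the same 4 arrays, so they are no independent evidence on Xist. A different sex makeup stays open as the explanation, and a sex difference between the groups cannot be told apart from their age for other genes.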
